A study of Mus musculus with 9 samples.

How the data were processed

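RNA was measured by sequencing in 9 libraries of MOVAS, an immortalised mouse aortic smooth muscle cell line. Per the labels' protocols, RNA was purified on silica columns and libraries were built and sequenced by BGI on its DNA nanoball platform. The submitters' processing notes name STAR, HTSeq and the genome build mm10, without versions. The deposited values are whole-number counts of reads per gene in 1 table of 53379 rows and 9 sample columns, and per the labels nothing says which strand setting the authors gave to the counting program or whether the library kit marked the strand. Totals ran from 1132822 to 1342286 counts per library. These totals hold only reads assigned to a row, so they do not give the sequencing depth. Precision is limited for rows of few counts.

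The strand was inferred from the values. Row identifiers were matched to GENCODE mouse release M21 on mm10, and 53274 of the 53379 rows had a match. Each row was classed by what lies on the opposite strand: an overlapping coding exon, a noncoding exon, an intron, the 5000 bp beyond the end of a gene, or none of these. The counts lay almost entirely in rows that overlap an exon on the opposite strand. Strand-marked libraries counted with the opposite setting would give this outcome, but only a recount from the reads could settle it. Rows were therefore analysed in 2 ways. The first used the rows under their own names, as planned. The second, chosen after seeing the data, read each row as its opposite-strand gene: rows whose exons overlap those of exactly 1 protein-coding gene on the opposite strand, by at least 50 bp, were kept, and the row with the highest mean count stood for each such gene. This gave 4115 genes, of which 2444 passed the filter. A value of this kind covers only the part of the gene's exons that the row overlaps. It cannot be separated from reads of neighbouring transcripts on that strand. A total of 703 rows lay within exons of another row on the same strand, so rows were not summed.

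Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, and the quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, in 1 fit of the 3 groups of 3 libraries with 6 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 was called changed. The 3 contrasts were DON against control, DON plus glutamate against DON, and DON plus glutamate against control. Standard errors are those implied by the test statistic, on the log2 scale. CPM values use TMM-adjusted totals of the tested rows, or of the tested opposite-strand genes. The same counts therefore give a higher CPM as an opposite-strand gene than as a row. The filter kept 4731 rows. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

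A total of 33 gene lists were fixed, and those with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Counts of list members are given over all genes tested and adjusted over the list alone. Most members of each list had no measured opposite-strand value, so these counts speak only for the measured members.

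The design, the lists, the rule for named genes and the first group of alternatives below were chosen before the data were examined. The rule took, per comparison, the 10 largest rises and 10 largest falls (6 and 6 for DON plus glutamate against control) with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between libraries of the groups, leaving out predicted gene models and pseudogenes. It also allowed the 3 members of each list with the smallest p, and a fixed set that included Gls2, Glul, Asns, Acta2, Tagln, Myh11, Cnn1, Ddit3 and Atf4. Applying the same rule to opposite-strand genes was decided after seeing the data. Outside the rule, these were singled out after their values were seen: Psph, Cebpb, Kif20a, Nars, Slc38a1 and Gm25579 in DON against control, Slc6a9, Atf5, Hmgcs1 and mt-Nd6 in DON plus glutamate against DON, and Ccna2 and Cyp51 in DON plus glutamate against control.

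Alternatives were DESeq2 1.42.0 size factors, library totals without composition factors, other filters, the DESeq2 Wald test, limma voom, the replicate number as a block, adjusted p under 0.01, a 1.5-fold minimum (glmTreat), only the groups compared, and each library left out in turn. Further ones chosen after seeing the data were the share of counts in coding rows with no opposite gene as a covariate, 1 row per group of rows whose exons overlap on the same strand, and an overlap of at least 200 bp.

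The tests were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. For DON against control over the 4731 rows, the share recovered was 18% at 1.25-fold, 40% at 1.5-fold, 64% at 2-fold and 88% at 3-fold, and 0.9% of the calls were false. For DON plus glutamate against DON over the 4731 rows, the shares were 10%, 48%, 70% and 94%, with 3.5% false calls. Over the 2444 opposite-strand genes, that comparison recovered 20%, 62%, 90% and 92%, with 6.4% false calls. For DON against control over those genes, 32%, 68%, 92% and 98% were recovered, with 2% false calls, and for DON plus glutamate against control 30%, 66%, 84% and 98%, with 6.1% false calls. For DON plus glutamate against control over the 4731 rows, 22%, 52%, 86% and 92% were recovered, with 2.3% false calls. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.07 to 3.28 over 9 pairs, so no library was a copy of another. Figures were drawn with matplotlib 3.10.9.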

Results

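MOVAS cells, smooth muscle cells of the mouse aorta immortalised for culture, were studied after 24 h in 3 conditions with 3 libraries each: untreated control, DON, and DON with glutamate. DON is a glutamine analogue that blocks glutamine-using enzymes. The labels give 50 mM DON and 2 mM glutamate. A micromolar dose of DON would be more usual, and the catalogue number printed beside glutamate may belong to a glutamine dipeptide. The counts settle neither point, so glutamate below means the compound so labelled. The series concerns GLS2, an enzyme of glutamine use, and the artery wall, and its comparisons ask what blocking glutamine use changed in these cells and what added glutamate restored. Libraries held from 1132822 to 1342286 counts.

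The counts lay mostly in rows with an expressed gene on the opposite strand. Rows that overlap a coding exon on the opposite strand were 10.3% of the table and took 88.0% ± 0.40 of the counts (SD, n = 9 libraries), whereas rows with no opposite gene were 62.3% of the table and took 1.35% ± 0.14. The row of Actb, the abundant cytoskeletal actin, held 4 to 27 counts per library, and that of Gapdh, an abundant glycolytic enzyme, held 35 to 47. The 83 ribosomal protein rows together took at most 0.079% of the counts of any library. Rows of smooth muscle and glutamine genes therefore say little of those genes: per library, Acta2 had 1 to 14 counts, Myh11 0 to 2, Cnn1 0 to 2, Col1a1 5 to 11, Asns 0 to 4, Atf4 1 to 9 and Gls2 9 to 26, the last lying opposite Spryd4. Below, a gene is named by what its row reads on the opposite strand, with the row given beside it, and each value covers only the overlapping part of that gene. In every gene given as changed, the 3 libraries of one group all lay above or all below the 3 of the other.

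**Figure D1:**
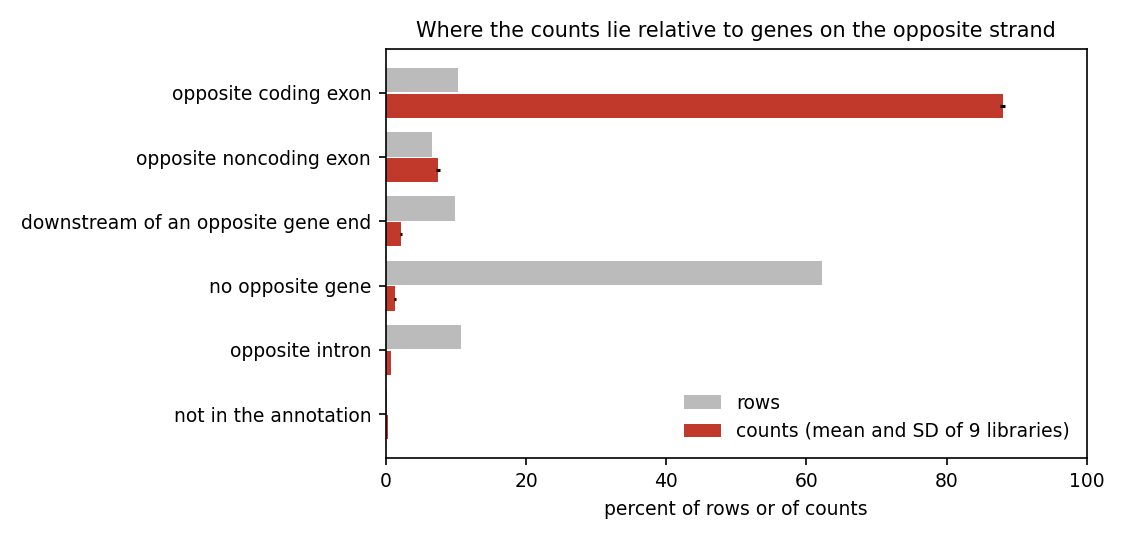
Percent of the 53379 rows (grey) and of the counts (red, mean and SD of 9 libraries) by what lies opposite the row. Rows opposite a coding exon are 10.3% of rows and hold 88.0% of counts.

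**Figure D2:**
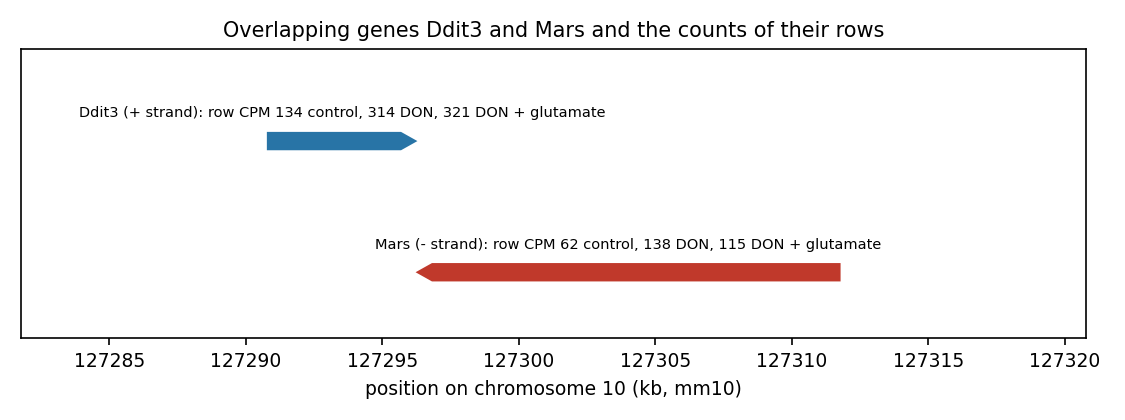
Ddit3 and Mars on chromosome 10 (kb, mm10), drawn as arrows in the direction of transcription, with the mean CPM of each gene's row in the 3 groups. The genes overlap by 68 bp at their ends, and the row named Ddit3 had a mean of 133.7 CPM in control and 314.4 in DON.

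DON against control asks what blocking glutamine use changed. Of the 32 genes in the amino acid starvation response list 6 were measured, and 5 of these rose, also 5 when adjusted over the list alone. Aldh1l2, a mitochondrial folate enzyme, rose 4.40-fold (log2 2.14 ± 0.08, SE; row D10Wsu102e), from 812.2 ± 54.0 to 3570 ± 212 CPM (SD, n = 3). Slc6a9, a glycine transporter, rose 3.46-fold (1.79 ± 0.07; row Ccdc24), and Atf5, a stress transcription factor, rose 3.29-fold (1.72 ± 0.11; row Nup62). Aldh1l2 lies on the minus strand of chromosome 10 (mm10) at 83487450 to 83534140, and its row on the plus strand overlaps its exons by 1056 bp. Slc6a9 lies on the plus strand of chromosome 4 at 117834506 to 117875198, with 1429 bp of overlap. Ddit3, a stress transcription factor, rose 2.24-fold (1.16 ± 0.13; row Mars), and Mars, the methionyl-tRNA synthetase, rose 2.36-fold (1.24 ± 0.10; row Ddit3). Ddit3 and Mars overlap by 68 bp, and the row of Atf5 by 82 bp, so these values rest on short stretches. By the opposite-strand reading the strand separates Ddit3 from Mars, and only reads given the wrong strand could mix them. The Ddit3 row held 161 to 431 counts per library, where the Atf4 row held 1 to 9 and the Actb row 4 to 27. The share of such reads at Ddit3 and Mars themselves was not measured. Psph, a serine synthesis enzyme, did not pass (log2 -0.07, adjusted p = 0.84). The list was higher by camera (adjusted p = 2.05e-44; with an estimated correlation, adjusted p = 0.000129).

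Of the 25 genes in the cholesterol synthesis list 6 were measured, and 5 of these fell, also 5 adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, was 2.23-fold lower (log2 -1.16 ± 0.07, SE; row AC123738.2), from 3235 ± 72.3 to 1449 ± 92.7 CPM (SD, n = 3). Lss, lanosterol synthase, was 2.06-fold lower (-1.04 ± 0.10; row 4930483K19Rik), and Idi1, an isoprenoid isomerase, was 1.84-fold lower (-0.88 ± 0.18; row AC124732.1). Hmgcs1 lies on the plus strand of chromosome 13 at 119690379 to 119708260, and 557 bp of its exons lie opposite the row. The list was lower by camera (adjusted p = 2.48e-19; adjusted p = 0.000822 with an estimated correlation).

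All 3 measured YAP and TGF-beta targets, of 22 listed, fell, over all genes and over the list alone. Thbs1, a matrix glycoprotein, was 1.58-fold lower (log2 -0.66 ± 0.07, SE; row Gm29233), Tgfb2, a TGF-beta ligand, 1.97-fold lower (-0.98 ± 0.26; row Gm29491), and Ccn2, a matrix-associated growth factor, 1.32-fold lower (-0.40 ± 0.10; row Gm15270). The list was lower by camera (adjusted p = 0.000135), with adjusted p = 0.0567 with an estimated correlation. Of 22 smooth muscle contractile genes listed 3 were measured, of which 2 fell, and 3 adjusted over the list alone. Tagln, an actin-binding protein of smooth muscle, was 1.42-fold lower (-0.51 ± 0.12; row AC122273.1). The other was Smtn, a smooth muscle cytoskeletal protein (-0.29 ± 0.09; row Gm11946). The contractile list was lower by camera (adjusted p = 0.0411; adjusted p = 0.149 with an estimated correlation). The contractile list did not pass without control replicate 2 (adjusted p = 0.0852) or DON replicate 1 (0.106), with a range of 0.0178 to 0.149 over the alternatives. Single calls ended for Smtn without control replicate 1 (adjusted p = 0.106), control replicate 2 (0.197), DON replicate 1 (0.0588) or DON replicate 2 (0.184), by DESeq2 (0.0526), and with library totals (0.0603), the replicate block (0.0572) or the covariate (0.0676; range over the alternatives 0.00784 to 0.197). They also ended for Tagln without control replicate 2 (adjusted p = 0.0627, range over the alternatives 0.00011 to 0.0627), for Tgfb2 without control replicate 2 (0.0937) or DON replicate 2 (0.0775) and by DESeq2 (0.0514; range 0.00645 to 0.0937), and for Ccn2 without control replicate 1 (0.0514), control replicate 2 (0.0704) or DON replicate 3 (0.0583; range 0.000704 to 0.0704).

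Of 30 G2 and mitosis genes listed 9 were measured, of which 4 fell, 5 adjusted over the list alone. Plk1, a mitotic kinase, was 1.31-fold lower (log2 -0.39 ± 0.07, SE; row Gm44985), and Prc1, a spindle midzone protein, 1.24-fold lower (-0.30 ± 0.07; row Rccd1; adjusted p = 0.0554 without DON replicate 3, range over the alternatives 0.000658 to 0.0554). The other 2 were the mitotic kinesins Kif4 (-0.39 ± 0.10; row Pdzd11; adjusted p = 0.0548 without control replicate 3, range 0.00249 to 0.0548) and Kif20a (-0.22 ± 0.07; row Cdc23). The Kif20a call ended without control replicate 2 (adjusted p = 0.130), control replicate 3 (0.247), DON replicate 1 (0.190), DON replicate 2 (0.0521), DON replicate 3 (0.121) or DON plus glutamate replicate 2 (0.0583), and with DESeq2 size factors (0.0501), library totals (0.0790), the replicate block (0.0739), the covariate (0.0689) or an overlap of 200 bp (0.0515), with a range of 0.0234 to 0.247 over the alternatives. The list had camera adjusted p = 0.0126, and adjusted p = 0.110 with an estimated correlation. Interferon-stimulated genes fell in 3 of 5 measured members (33 listed), 3 adjusted over the list alone. The interferon list had camera adjusted p = 0.0411, and adjusted p = 0.375 with an estimated correlation. Dhx58, a viral RNA sensor, was 1.36-fold lower (-0.45 ± 0.09; row Dhx58os), and Usp18, an ISG15 protease, was at log2 -0.32 ± 0.08 (row Gm44148). The third was Ifi35, an interferon-induced protein (-0.23 ± 0.07; row Gm11626), whose call ended without control replicate 1 (adjusted p = 0.0912), control replicate 2 (0.122), control replicate 3 (0.0964), DON replicate 1 (0.116) or DON replicate 3 (0.113), and with library totals (0.0724) or the replicate block (0.0502), with a range of 0.0243 to 0.122. The p53 target list was higher (camera adjusted p = 0.000135; adjusted p = 0.0376 with an estimated correlation), and 1 of its 4 members passed over all genes, 2 over the list alone. That member was Gadd45a, a growth arrest gene also raised by other stresses, at 3.31-fold (1.73 ± 0.09; row E230016M11Rik). The tRNA synthetase list was higher (adjusted p = 0.0135; adjusted p = 0.111 with an estimated correlation) with Mars called of 3. Over the list alone 1 was higher and 1 lower, Hars, the histidyl-tRNA synthetase, at log2 -0.30 ± 0.10 (adjusted p over all genes 0.0518). Hars passed in some alternatives, among them with no filter on low counts (adjusted p = 0.0112). It also passed without DON replicate 1 (adjusted p = 0.00497), DON plus glutamate replicate 1 (0.0302) or DON plus glutamate replicate 3 (0.0416), with a range of 0.00497 to 0.274 over the alternatives. NF-kB and cytokine genes fell in 2 of 3 measured members (32 listed), 3 adjusted over the list alone (adjusted p = 0.0428; adjusted p = 0.149 with an estimated correlation). The 2 were Cxcl10, a chemokine (-0.49 ± 0.15; row Art3), and Nfkb2, an NF-kB subunit (-0.27 ± 0.08; row Psd). The Cxcl10 call ended without control replicate 1 (adjusted p = 0.0542), control replicate 2 (0.131), control replicate 3 (0.0782), DON replicate 1 (0.132) or DON replicate 2 (0.0911), by DESeq2 (0.0938) and with the covariate (0.0757; range 0.0200 to 0.132). The Nfkb2 call ended without control replicate 1 (0.164), control replicate 2 (0.0771), DON replicate 1 (0.0642) or DON replicate 2 (0.0663) and with the covariate (0.0610; range 0.01005 to 0.164). Without DON replicate 1 the interferon (adjusted p = 0.0750), synthetase (0.0750) and NF-kB (0.126) lists did not pass, nor did the interferon list without control replicate 2 (0.124) or the NF-kB list without control replicate 1 (0.0571) or control replicate 2 (0.0669). Over the alternatives these 3 lists ranged from 0.0255 to 0.375, 0.00353 to 0.111 and 0.00566 to 0.149.

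Of the other lists, Glul, glutamine synthetase, was 1.48-fold lower (log2 -0.56 ± 0.15, SE; row Teddm2; adjusted p = 0.0109), the 1 of 4 measured glutamine and glutamate genes that passed. The call ended without control replicate 2 (adjusted p = 0.0577), control replicate 3 (0.0624) or DON replicate 1 (0.0898), with a range of 0.000658 to 0.0898 over the alternatives. None of 5 measured collagen and elastic matrix genes (34 listed) passed (camera adjusted p of the list = 0.658), with Fn1, fibronectin, at log2 0.08 ± 0.09. Gnpnat1, a hexosamine enzyme, rose 1.33-fold (0.41 ± 0.08; row Styx), the 1 of 4 hexosamine and hyaluronan genes that passed over all genes and over the list alone. Of 3 measured matrix proteases and inhibitors 1 was higher, as was 1 of 8 purine and pyrimidine and 1 of 5 ribosome biogenesis genes. Hypoxia-response genes had 1 higher and 1 lower of 7. Glycolysis had 1 of 5 lower and collagen crosslinking 1 of 3 lower. None of these lists passed by camera. Markers of endothelial cells, leukocytes and epithelium had 0 measured opposite-strand genes, and of fibroblast markers only Pdgfra was measured, 3.35-fold lower (-1.74 ± 0.41; row Gm42803; log2 -2.49 to -1.43 without 1 library). Its level was low, 21.7 ± 2.0 CPM in control and 6.4 ± 4.6 in DON (SD, n = 3). Outside the lists, the largest rises included Angptl6, a secreted angiopoietin-like protein (7.01-fold, 2.81 ± 0.23; row A230050P20Rik), Apobr, an apolipoprotein B receptor (5.52-fold, 2.46 ± 0.15; row Cln3), and Trim46, a microtubule-organising protein (4.43-fold, 2.15 ± 0.20; row Krtcap2).

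By edgeR's quasi-likelihood test, 283 of 2444 opposite-strand genes changed, 125 higher and 158 lower, and 702 had no overlap between the libraries of the groups, where chance gives 10%. Of the 4731 rows under their own names, 299 changed, 125 higher and 174 lower, and no list passed under those names (0 of the lists by camera, 0 with an estimated correlation and 0 by fry), though 1, 3, 1 and 3 did by camera without control replicate 3, DON replicate 2, DON replicate 3 and DON plus glutamate replicate 2. With library totals in place of TMM factors the split became 180 higher and 126 lower for rows and 152 higher and 116 lower for opposite-strand genes. Without control replicate 1, control replicate 2, DON replicate 2 or DON replicate 3 the opposite-strand count was 186, 142, 180 or 178, and the row count 183, 176, 173 or 182.

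**Figure D3:**
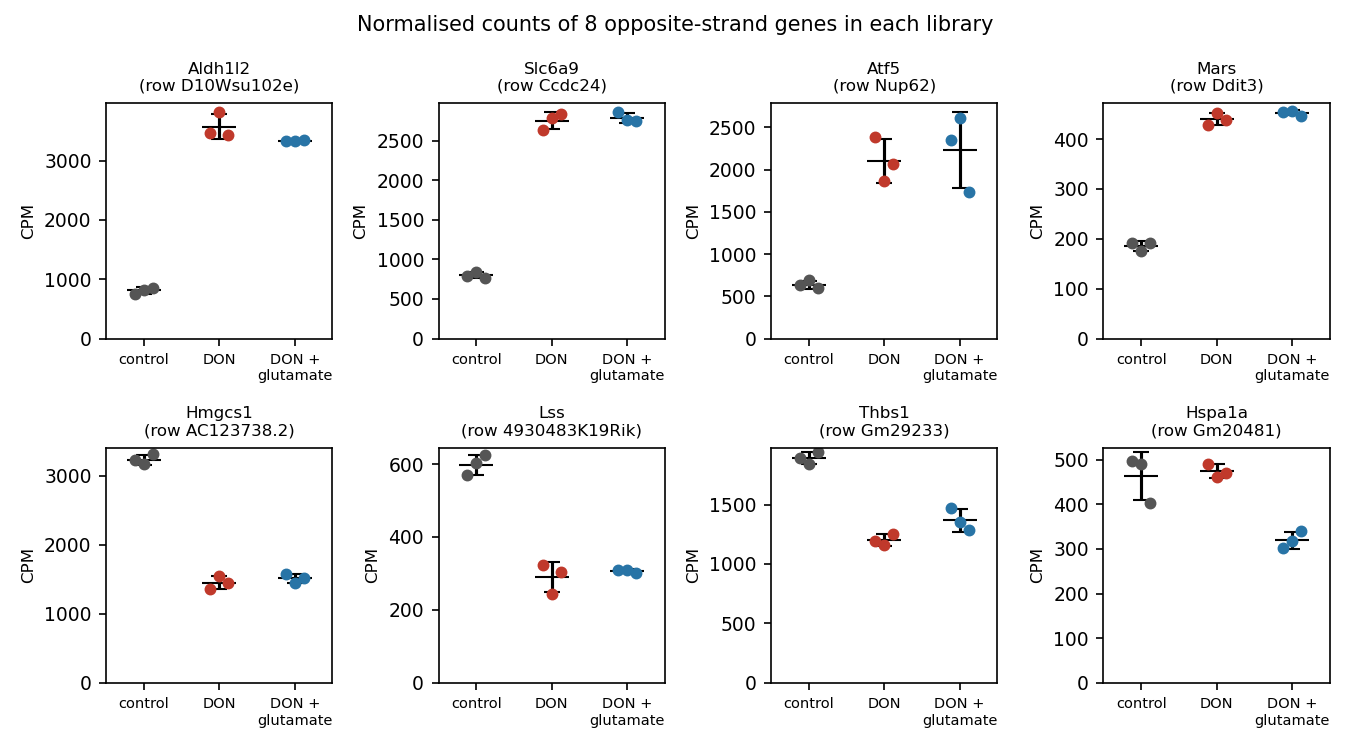
CPM of 8 opposite-strand genes in each library (points), with the mean and SD of each group of 3 (bars). Aldh1l2 averaged 812.2 CPM in control, 3570 in DON and 3336 in DON plus glutamate. Hspa1a averaged 474.3 CPM in DON and 319.9 in DON plus glutamate.

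DON plus glutamate against DON asks what the added glutamate changed under the inhibitor. Hspa1a, the inducible heat shock protein, was the opposite-strand gene that passed: it was 1.49-fold lower (log2 -0.57 ± 0.10, SE; row Gm20481), at 474.3 ± 15.9 CPM in DON and 319.9 ± 18.9 with glutamate (SD, n = 3), with adjusted p = 0.00452. Hspa1a lies on the minus strand of chromosome 17 at 34969190 to 34972156. The call ended without DON plus glutamate replicate 1 (adjusted p = 0.0616) or replicate 2 (0.0641), with a range of 3.6e-05 to 0.0641 over the alternatives. Against control, Hspa1a was also lower in DON plus glutamate, at log2 -0.62 to -0.48 without 1 library. Its adjusted p there ranged from 6.35e-06 to 0.00864 over the alternatives. In DON against control, 0 of 3 measured heat shock genes passed over all genes. The Hspa1a call therefore does not show a DON change that glutamate restored. Of genes that DON raised, Aldh1l2 was at log2 -0.10 ± 0.07, Slc6a9 at 0.02 ± 0.07 and Atf5 at 0.09 ± 0.10. Of cholesterol genes Hmgcs1 was at 0.06 ± 0.07, and none of these 4 passed. Lower without passing were Cebpb, a stress-related transcription factor that DON raised (log2 0.34 ± 0.09 against control; row Tmem189), at -0.27 ± 0.09 (adjusted p = 0.468, range over the alternatives 0.254 to 0.892), and Ddit3, at -0.25 ± 0.11 (adjusted p = 0.643, range 0.500 to 0.995). Of the 6 starvation response genes 0 passed over all genes and 1, Cebpb, was lower over the list alone (camera adjusted p = 0.319; adjusted p = 0.529 with an estimated correlation). Without DON replicate 2 or DON plus glutamate replicate 3 the count of changed genes was 2 or 3, and it was 0 without DON plus glutamate replicate 1 or replicate 2.

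The 3 YAP and TGF-beta targets passed, all with higher values under glutamate, when adjusted over the list alone, and 0 of 3 passed over all genes: Ccn2 at log2 0.34 ± 0.10 (SE), Tgfb2 at 0.67 ± 0.27 and Thbs1 at 0.19 ± 0.07. The list was higher by camera (adjusted p = 0.00121), with adjusted p = 0.303 with an estimated correlation, and the call ended without DON plus glutamate replicate 1 (adjusted p = 0.0796) and by fry (0.221), with a range of 6.47e-06 to 0.303 over the alternatives. Tagln was at log2 0.53 ± 0.12 without passing (adjusted p = 0.204). Of 3 measured contractile genes 0 passed over all genes and 1, Tagln, was higher over the list alone. The contractile list did not pass (camera adjusted p = 0.319; adjusted p = 0.529 with an estimated correlation), with a range of 0.0382 to 0.735 over the alternatives. Without DON plus glutamate replicate 3, Tagln (adjusted p = 0.00701) and Ccn2 (0.00969) passed, as did Tagln with no filter on low counts (0.00138). Over the alternatives Tagln ranged from 0.00138 to 0.753 and Ccn2 from 0.00969 to 0.893. The YAP and TGF-beta targets and Tagln had fallen in DON against control, and this contrast uses the same DON libraries. Noise that lowered them in those libraries would also make them look raised here. Where no simulated group differed, fold changes in these contrasts correlated at -0.485 on average over opposite-strand genes. Whether glutamate reversed the DON change is therefore left open, as for Cebpb and Ddit3 above.

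Under their own names, 7 of 4731 rows changed, 5 higher and 2 lower. The 5 that rose were mitochondrial: mt-Tt (log2 1.32 ± 0.22, SE), mt-Cytb (2.26-fold, 1.18 ± 0.22), mt-Ti (2.24-fold, 1.16 ± 0.22), mt-Nd1 (2.05-fold, 1.04 ± 0.20) and mt-Nd2 (1.73-fold, 0.79 ± 0.12). These genes lie on the plus strand, so by the opposite-strand reading their rows count minus-strand RNA and not the named genes. The row named for H2-T24, a class I histocompatibility gene, was 1.59-fold lower (-0.67 ± 0.13). It lies opposite an intron, so it may not measure H2-T24. The other row that fell, Gm20481, reads Hspa1a. Of 7 measured mitochondrially encoded rows 3 rose, and 6 adjusted over the list alone (camera adjusted p = 5.13e-13; adjusted p = 0.0209 with an estimated correlation, 0.219 by fry). Without DON plus glutamate replicate 2, mt-Nd2 passed (adjusted p = 0.0322) and mt-Nd1 (0.357), mt-Cytb (0.0769), mt-Ti (0.302) and mt-Tt (0.0684) did not, and 1 row changed in all. Without DON replicate 3, 1 row changed, and without DON plus glutamate replicate 3, 11. By DESeq2, mt-Tt (0.189), mt-Cytb (0.880), mt-Ti (0.0669), mt-Nd1 (0.890) and H2-T24 (0.234) did not pass. By voom, mt-Cytb, mt-Ti, mt-Nd1 and H2-T24 did not pass (each 0.0589), nor did they with only the groups compared (0.0512, 0.0582, 0.0648 and 0.0591). The mt-Ti call also ended without DON replicate 1 (0.0515), DON replicate 3 (0.236) or DON plus glutamate replicate 1 (0.0660). Without DON replicate 3, mt-Tt (0.0673), mt-Cytb (0.176) and mt-Nd1 (0.300) did not pass either. The H2-T24 call also ended with the replicate block (0.0787) and without DON replicate 1 (0.0861), DON replicate 2 (0.145), DON replicate 3 (0.138), DON plus glutamate replicate 1 (0.0866) or DON plus glutamate replicate 2 (0.302). Over the alternatives the adjusted p of mt-Nd2 ranged from 5.02e-12 to 0.0322, that of mt-Nd1 from 7.49e-13 to 0.890, that of mt-Cytb from 8.13e-25 to 0.880, that of mt-Ti from 3.73e-05 to 0.302, that of mt-Tt from 3.16e-18 to 0.189 and that of H2-T24 from 0.0185 to 0.302.

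Counted as changed by DON and moved back by glutamate were 2 rows, mt-Nd2 (log2 -0.48, then 0.79) and the row named H2-T24 (0.45, then -0.67), whose second call was lost in the alternatives given above, and 0 opposite-strand genes by edgeR, 0 by DESeq2 and 0 by voom. The row count was 1 without control replicate 1, control replicate 3, DON replicate 3 or DON plus glutamate replicate 2, 0 without control replicate 2 or DON replicate 1, and 4 without DON plus glutamate replicate 3. The opposite-strand count was 1 without DON replicate 2 and 2 without DON plus glutamate replicate 3. In DON against control, mt-Nd2 did not pass without control replicate 2 (adjusted p = 0.124) or DON replicate 1 (0.0728; range over the alternatives 0.000172 to 0.124). In 20 simulations in which glutamate changed nothing and the DON libraries were shared, the highest such count was 0 for rows and 0 for opposite-strand genes. Unadjusted p under 0.05 was reached by 174 of the 2444 opposite-strand genes in this contrast. The covariance of log2 fold changes, DON against control with DON plus glutamate against DON, was -0.0283 over opposite-strand genes, against -0.0173 on average in those simulations (range -0.0221 to -0.0131), a difference of -0.0111. The simulations hold no correlation between genes.

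DON plus glutamate against control asks what still differed from untreated cells. Measured genes of the amino acid starvation response were higher: 4 of 6 passed, 4 adjusted over the list alone. Aldh1l2 was 4.11-fold higher (log2 2.04 ± 0.08, SE), Slc6a9 3.50-fold (1.81 ± 0.07), Atf5 3.49-fold (1.80 ± 0.11) and Ddit3 1.88-fold (0.91 ± 0.13). Cholesterol synthesis was lower in 4 of 6 members, 6 adjusted over the list alone, with Hmgcs1 2.14-fold lower (-1.10 ± 0.07) and Lss 1.96-fold lower (-0.97 ± 0.10). Cyp51, a sterol demethylase (-0.54 ± 0.12; row Akap9), did not pass without DON plus glutamate replicate 2 (adjusted p = 0.0712, range over the alternatives 0.00137 to 0.0712). The list calls held for both (camera adjusted p = 1.92e-47 and 1.61e-19; with an estimated correlation, adjusted p = 0.000105 and 0.000799). Of G2 and mitosis genes 4 of 9 were lower, 4 adjusted over the list alone (camera adjusted p = 0.000243; adjusted p = 0.0281 with an estimated correlation), with Plk1 at log2 -0.48 ± 0.08 and Prc1 at -0.36 ± 0.07. The other 2 calls ended without some libraries: that of Kif20a (-0.28 ± 0.07) without control replicate 2 (adjusted p = 0.0675), control replicate 3 (0.162), DON plus glutamate replicate 2 (0.0899) or DON plus glutamate replicate 3 (0.0990; range over the alternatives 0.00316 to 0.162), and that of Ccna2, cyclin A2 (-0.28 ± 0.08; row Exosc9), without control replicate 1 (0.0536), control replicate 2 (0.0625), control replicate 3 (0.127) or DON plus glutamate replicate 2 (0.139) and with the covariate (0.0529; range 0.00288 to 0.139). The tRNA synthetase list (camera adjusted p = 7.92e-05; adjusted p = 0.0273 with an estimated correlation) and the p53 target list (1.08e-05, and 0.0199 as adjusted p with an estimated correlation) were higher, with 1 of 3 and 1 of 4 members called and 2 of each adjusted over the list alone. Interferon-stimulated genes were lower in 2 of 5 members, 3 adjusted over the list alone (camera adjusted p = 0.0438; adjusted p = 0.315 with an estimated correlation), and the list did not pass without control replicate 2 (0.127), without DON plus glutamate replicate 1 (0.161) or with the replicate number as a block (0.0517), with a range of 0.0141 to 0.315 over the alternatives. The call of Usp18 (-0.33 ± 0.08) ended without DON plus glutamate replicate 1 (adjusted p = 0.0834, range over the alternatives 0.00207 to 0.0834). Of YAP and TGF-beta targets 1 of 3 was lower, also 1 adjusted over the list alone: Thbs1, 1.38-fold lower (-0.47 ± 0.07). That list did not pass (camera adjusted p = 0.0532; adjusted p = 0.227 with an estimated correlation), though it did without control replicate 1 (adjusted p = 0.0491), control replicate 3 (0.0490) or DON plus glutamate replicate 1 (0.0160) and by fry (0.0157), with a range of 0.0157 to 0.227 over the alternatives. Of 3 contractile genes 0 passed over all genes, and 2 were lower adjusted over the list alone (camera adjusted p = 0.179; adjusted p = 0.315 with an estimated correlation): Smtn (-0.29 ± 0.09) and Vcl, vinculin (-0.20 ± 0.07; row Ap3m1). Smtn passed over all genes in some alternatives, among them without DON replicate 2 (adjusted p = 0.0339) or DON plus glutamate replicate 1 (0.0260), with a range of 0.0124 to 0.284 over the alternatives. Tagln was at log2 0.02 ± 0.12 and Glul at -0.20 ± 0.14, neither past the threshold.

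By edgeR's quasi-likelihood test 131 of 2444 opposite-strand genes changed, 64 higher and 67 lower, and 153 of 4731 rows, 67 higher and 86 lower. With library totals the splits were 82 higher and 51 lower for genes and 104 higher and 50 lower for rows. Without control replicate 2, control replicate 3 or DON plus glutamate replicate 2 the opposite-strand count was 83, 77 or 73, and without control replicate 2 or DON plus glutamate replicate 2 the row count was 99 or 88. Of opposite-strand genes, 53 were higher and 50 lower in both treatments against control, where independent lists would share 3.27 and 4.33. Simulated unchanged groups shared 0 and 0. Few genes can pass where no group differs, so those counts do not measure what shared controls add. Simulations in which glutamate changed nothing shared more, 111 (range 96 to 125) and 116 (98 to 133), with a correlation of 0.86 (0.84 to 0.87) and a covariance of 0.109 (0.101 to 0.116). Their fold changes are the fitted ones with noise included, which raises these values. The correlation of fold changes across genes was 0.80, against 0.51 for unchanged groups that share these controls, and the covariance 0.0795 against 0.0184, a difference of 0.0611. With 3 controls, no split gives both parts 2 libraries, so part of the excess of shared genes over independent lists may come from the shared controls. Genes are not independent replicates.

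**Figure D4:**
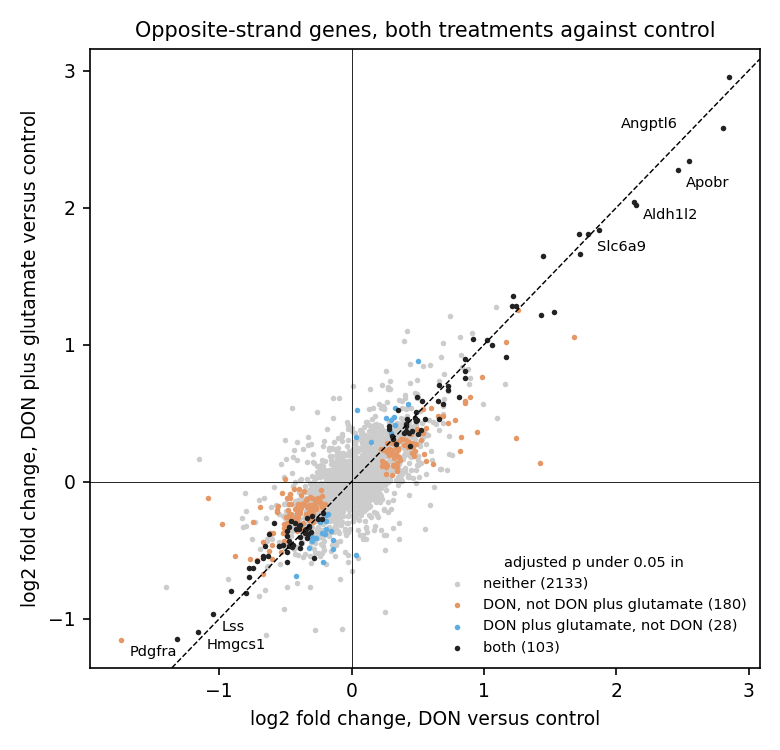
Log2 fold change of 2444 opposite-strand genes in DON plus glutamate against control (vertical axis) and in DON against control (horizontal axis), coloured by where adjusted p was under 0.05; the dashed line marks equal change. In both contrasts 103 genes passed.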

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

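The opposite-strand analysis with all its alternatives, the covariate and the single row per overlapping group were chosen after seeing the data. Of 2804 alternative values of 143 named results, each a gene in 1 comparison, 2498 kept their direction and side of the threshold, 77 were lost under the 1.5-fold minimum and 203 under others, 15 gained it and 11 changed direction, each without passing. The last were Fn1 (log2 -0.0073 with the covariate, -0.0032 to 0.1932 without 1 library) and Psph (-0.2094 to 0.078) for DON, Slc6a9 (-0.0125 to 0.0391), Atf5 (-0.04 to 0.2362) and the mt-Nd6 row (-0.275 to 0.054) for glutamate, and Tagln (-0.1636 to 0.1581) for DON plus glutamate against control. DESeq2 gave no adjusted p for some low-count genes, which were left out. Precision is limited in rows of few counts.

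For rows, in the order DON against control, DON plus glutamate against DON, DON plus glutamate against control, moved back, adjusted p under 0.01 gave 136, 3, 79 and 0 and the 1.5-fold minimum gave 24, 0, 21 and 0, by construction. The glutamate contrast gave 15 with no filter, 12 at 1 CPM, 2 by DESeq2, 3 by voom and 3 with only the groups compared; moved back gave 5 with no filter, 1 by DESeq2, 1 by voom and 4 with the covariate. Ranges without 1 library were 173 to 318, 1 to 11, 88 to 178 and 0 to 4. Row lists ranged from 0 to 3 for DON and 0 to 3 for DON plus glutamate against control, the latter 0 with an estimated correlation and 0 by fry; the glutamate list was 0 by fry. For opposite-strand genes, adjusted p under 0.01 gave 127 for DON and 66 for DON plus glutamate against control, the 1.5-fold minimum 19, 0 and 16, no filter 4 in the glutamate contrast and 1 moved back, and an overlap of 200 bp gave 176 for DON. Without 1 library the ranges were 142 to 292, 0 to 3, 73 to 154 and 0 to 2. Lists gave 3 and 0 with an estimated correlation for DON and for glutamate, 0 by fry for glutamate and 10 by fry for DON plus glutamate against control, with ranges of 5 to 9 for DON and 0 to 2 for glutamate. Apart from the stricter thresholds, the cause was not tested.

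With the replicate number as a block, rows gave 221, 6, 117 and 1. Opposite-strand genes gave 215, 1, 109 and 0. The numbers do not pair the libraries: deviations of same-numbered libraries correlated from -0.195 to 0.154 over 9 pairs, 1 of them over 0.1, and 2 of 9 libraries matched their own number best.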

Other observations

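Of the tests below, those on the strand of the counts, on the mitochondrial rows and on a transcript from Eif3c into Apobr were chosen after their results had been seen. Some rows with no opposite gene, chosen after their values were seen, also moved: Nars, an asparaginyl-tRNA synthetase, was at log2 0.95 ± 0.29 (SE) in DON against control with adjusted p = 0.0448, and Slc38a1, a glutamine transporter, at 0.93 ± 0.28 with adjusted p = 0.0447. Both calls were lost in several alternatives, among them without DON replicate 1 (adjusted p = 0.227 and 0.206), with ranges of 0.000505 to 0.227 and 0.036 to 0.206 over the alternatives. Coding rows of this class together held 1.01% of counts in control and 1.11% in DON.

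The counts sit on the strand opposite to the expressed genes. Libraries that do not mark strand are argued against, since 2.26% of coding rows with no opposite gene reached a mean of 10 counts and 57.5% of those opposite a coding exon did. Rows holding each gene's own RNA at low depth are argued against by the ribosomal protein rows, at most 0.079% of any library. Rows that share an opposite gene without overlapping each other had a Spearman correlation of 0.498 in DON against control over 173 pairs, where neighbouring rows with different opposite genes had 0.0635, in line with strand-marked libraries counted with the opposite setting. The share of 10000 draws of neighbouring pairs at least as high was 1e-04, the smallest they can give, and genes are not independent replicates.

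Mitochondrial rows were higher in DON plus glutamate than in DON. A larger leaked share with glutamate is argued against for the group means. The mean share of counts in coding rows with no opposite gene had a ratio of 0.995 between the groups. By library this share was 0.973%, 1.254% and 1.071% in DON plus glutamate replicates 1 to 3. In DON it was 1.285%, 1.034% and 0.997%. A ratio of means cannot exclude more leak in DON plus glutamate replicate 2. DON plus glutamate replicate 2 alone is argued against only for mt-Nd2, at log2 0.79 with that library and 0.72 without it (edgeR adjusted p = 0.0322). The median log2 change of the list was 0.48 with it and 0.363 without it, but the median row changed from mt-Co1 to mt-Nd5. Without that library mt-Co1 went from 0.48 to 0.11 and mt-Cytb from 1.18 to 0.63, and several single calls ended. How much of the rise in the other rows that library carries stays open. Heavy-strand RNA higher alike over its whole length is argued against by mt-Nd6, the minus-strand row of the list, which by the opposite-strand reading counts such RNA directly: it was at log2 -0.09 (-0.0874) ± 0.12 (SE), or -0.275 to 0.054 without 1 library, where the plus-strand rows had a median of 0.64. Higher RNA of single heavy-strand transcripts read through a constant leak stays open: plus-strand rows of the list differed by up to 3.55 standard errors, beyond a first bound of 2, but that is the largest of many pairs and such transcripts can differ in stability. By the opposite-strand reading the plus-strand rows count light-strand RNA directly. An effect of glutamate on that RNA may therefore account for the pattern, which was not tested. In DON plus glutamate against control, 0 of the 7 rows passed over all rows (camera adjusted p = 0.133). Adjusted over the list alone, 4 were higher. In DON against control 2 of the 7 were lower, mt-Nd2 (log2 -0.48) and mt-Nd4 (-0.47, edgeR adjusted p = 0.00895). Noise that lowered rows in the shared DON libraries would also make them look raised with glutamate.

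Neighbouring minus-strand rows on chromosome 7 (mm10) rose with DON: Eif3c at 126546455 to 126566411 (log2 1.94 ± 0.18, SE), Gm25579 (2.58 ± 0.43), Cln3 (2.45 ± 0.15) and Il27 (3.01 ± 0.50, and 2.45 to 3.79 without 1 library), ending at 126594941. The Il27 row held 0 to 5 counts in control. Eif3c and Gm25579 have no annotated opposite gene, while Cln3 and Il27 lie opposite Apobr. A larger leaked share in DON is argued against by a median log2 change of 0.08 (0.0755) over 362 coding rows with no opposite gene. Plus-strand transcription through Eif3c into Apobr may account for the pattern as a hypothesis; Cln3 exceeded Eif3c by 2.19 standard errors of the difference, just beyond a first bound of 2, which leaves it open, since leaked Eif3c RNA in its row would dilute the fold.

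The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. In 1 of 10 splits, the real one, as many rows changed for DON against control (299, highest other 0), for DON plus glutamate against DON (7, highest other 4) and for DON plus glutamate against control (153, highest other 0). For opposite-strand genes the real counts and highest others were 283 and 0, 1 and 1, and 131 and 0, with 2 of 10 splits as large for the glutamate contrast.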
